A study of Mus musculus with 27 samples.

How the data were processed

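Polyadenylated RNA was sequenced from 27 libraries of mouse bone marrow lymphoid precursors on a C57BL/6 background, made with a low-input template-switching kit and a transposase-based library kit, per the labels' protocols. The groups, per the labels, were the all lymphoid progenitor (ALP, 7 libraries), the specified early innate lymphoid progenitor (sEILP, 5), the committed early innate lymphoid progenitor (cEILP, 6), the innate lymphoid cell precursor (ILCP, 3), and ALP cultured after transduction with a retrovirus for GFP alone (GFP, 3) or for NFIL3 and GFP (NFIL3, 3). Each library belonged to 1 of 2 batches (14 and 13 libraries). ILCP occurred in batch 2 only, and the transduced cells in batch 1 only. The reporter genotype was tied to the batch. Within batch 2 it was also tied to the group, since sEILP and cEILP carried a Zbtb16 reporter beside the Tcf7 reporter whereas ALP and ILCP carried a Tcf7 reporter alone. The labels give replicate numbers but do not say whether replicates came from separate animals, so every p-value measures only the spread between these samples, which may be technical.

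The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.39, STAR 2.7.10b, RSEM 1.3.2, limma and edgeR 3.36.0 with build mm39, without the role of each. The annotation version is not given in the sources used here, and no coordinates are printed because the annotation at hand belongs to another build. The count table deposited by the authors holds expected counts (RSEM estimated counts per Ensembl gene, not normalized), identified from the values: 71120 of them (4.623%) were not whole numbers. A further table deposited by the authors holds a normalized score per library and group means of that score, on a linear scale, by a normalization not given in the sources used here. Per the file headers, that deposited table also holds log2 fold changes for 3 comparisons, together with a p-value and an adjusted p-value for each, by a test not given in the sources used here. The deposited group means were compared with the library columns, and the value for cEILP averages 7 libraries, among them the library labelled sEILP in batch 1, replicate 2, while the value for sEILP averages the other 4. The labels were followed throughout.

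The expected counts were rounded to whole numbers. Of 56980 genes in the table, 17641 received a symbol from the deposited normalized table, 34992 from a gene name list and 4347 none. Genes were filtered with filterByExpr by group within batch, which left 15568 tested genes, and libraries were scaled by TMM. In R 4.3.3, edgeR 4.0.16 fitted the quasi-likelihood model to all 27 libraries at once with 1 mean for each of 9 combinations of group and batch (18 residual degrees of freedom, prior degrees of freedom 3.784, common dispersion 1.202). Comparisons were made within a batch. Where both batches held both groups, the 2 within-batch differences were averaged with equal weight, and their difference was tested as an interaction. Adjusted p-values are Benjamini-Hochberg values over the tested genes, and a gene passed when its adjusted p was under 0.05. Levels are TMM-scaled CPM (counts scaled to the library), given as mean ± SD over libraries, and log2 fold changes are given ± SE.

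A fold against a group with no counts is a lower bound computed against a floor of 3 counts per library. Where a group held 1 to 3 counts, the ratio of summed counts per effective library size is given with its exact 95% Clopper-Pearson interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. At the depths found, 3 counts corresponded to between 0.186 and 0.545 CPM.

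Genes were named by a rule: per comparison, the 8 raised and 8 lowered genes (5 and 5 for GFP against ALP and NFIL3 against cEILP) with the largest absolute log2 fold change that passed, reached 10 CPM in the higher group and separated the groups fully within each batch, leaving out predicted, ribosomal, mitochondrial, histone and antigen receptor genes; up to 4 members of each list with the smallest adjusted p; and Nfil3 and the sort genes. The 22 lists were ILC precursor regulators, ILC precursor surface and signalling genes, multipotent and lymphoid progenitor, B lineage, T lineage, NK and cytotoxic, ILC2, ILC3 and LTi, myeloid, dendritic and plasmacytoid, mast cell and basophil, erythroid and megakaryocyte, stromal, cell cycle, circadian and D-box, Notch targets, E and Id proteins, immediate early and stress, interferon stimulated, glycolysis, cholesterol synthesis, and sort genes (the markers of the gates). Some genes stand in more than 1 list. Another 2 lists, MHC class I presentation (14 genes) and Y-linked genes with Xist (5 genes), were added after the values were seen. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, and again with an estimated correlation) and with fry, adjusted by Benjamini-Hochberg over the 22 lists within a comparison. Camera states whether the genes of a list ranked higher or lower than the other tested genes, and fry whether they changed at all.

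Signatures of up to 100 raised and 100 lowered genes of sEILP, cEILP and ILCP against ALP were taken from batch 2 alone, which shares no library with the transduced cells, and tested in NFIL3 against GFP. A score per library was the mean log2 CPM (prior count 2) of the raised cEILP signature genes minus that of the lowered ones, compared by a two-sided exact permutation test. The groups, comparisons, lists, naming rule and first set of alternatives were fixed before the data were examined.

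The procedure was tested on simulated data with the fitted dispersions, with 50 genes changed at each fold. In the layout of NFIL3 against GFP, edgeR recovered 1, 8, 13 and 22 of them at 2-, 4-, 8- and 16-fold, with 0 false among 44 calls, so a gene that did not pass may still differ by several fold. In the layout of sEILP against ALP it recovered 4, 14, 21 and 23, with 0 false among 62 calls. DESeq2 1.42.0 made 172 false among 249 calls and 252 among 355 in these layouts, and limma-voom made 2 among 22 and 8 among 59.

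Leaving out each library was also run for 4 further comparisons given in the closing section (cEILP, ILCP and NFIL3 against ALP, and NFIL3 against sEILP). Alternatives tried were DESeq2 size factors, no filter, DESeq2, limma-voom, only the libraries compared, replicate number as a block, an additive batch term, each batch alone, an absolute log2 fold change of at least 1 and leaving out each library in turn. Added after the data were seen were leaving out the 3 libraries with the fewest detected genes, limma-voom with quality weights, a robust quasi-likelihood fit, and counting the sEILP library of batch 1, replicate 2, as cEILP. Replicate numbers did not pair the libraries: of 44 same-number pairs, 0 had a residual correlation over 0.1 (from -0.06 to 0.05), so no pairing was used. Duplicated libraries were checked for, and none was found (chi-square per degree of freedom between replicates at least 28.16). No library was left out. Mitochondrial genes were not analysed here, since the 22 in the table held a total count of 23.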

Results

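Gene expression was measured by bulk RNA sequencing in 27 libraries of mouse bone marrow lymphoid precursors, set out to compare precursors made by forced expression of NFIL3 with innate lymphoid cell (ILC) precursors taken directly from animals. The directly sorted cells ran from the all lymphoid progenitor (ALP, 3 libraries in batch 1 and 4 in batch 2) through the specified early innate lymphoid progenitor (sEILP; 2 and 3) and the committed one (cEILP; 3 and 3) to the ILC precursor (ILCP; 3, batch 2 only). The cultured cells were ALP transduced with a retrovirus for GFP alone (GFP; 3) or for NFIL3 and GFP (NFIL3; 3), grown for 4 days on irradiated OP9 stroma with stem cell factor, Flt3 ligand and IL-7, and sorted as GFP-positive cells without the myeloid marker Mac1. Total counts per library ran from 5504946 to 13459992 in batch 1 and from 11206377 to 16150999 in batch 2. Genes with a count numbered 10672 to 14024 and 9925 to 14531, and ribosomal protein genes took 4.39 to 6.23% and 1.59 to 2.87% of counts. The 3 libraries with the fewest genes, namely cEILP replicate 3 of batch 1 (10672), sEILP replicate 3 of batch 2 (10048) and ILCP replicate 2 (9925), lacked 1.78%, 1.46% and 4.02% of 4449 abundant genes, against at most 0.472% in the others. Of the 27 libraries, 7 held Xist without Y-linked transcripts, 9 held Y-linked transcripts without Xist and 11 held both.

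Nfil3 (ENSMUSG00000056749), the transcription factor forced in the cultured cells, was low in ALP and high in sEILP. It stood at 23.3 ± 13.4 CPM in ALP of batch 1 (n = 3), 49.4 ± 20.9 in ALP of batch 2 (n = 4), 502.5 ± 77.8 and 594.3 ± 124.3 in sEILP (n = 2 and 3), 129.9 ± 47.8 and 207.2 ± 121.5 in cEILP (n = 3 and 3) and 36.3 ± 38.1 in ILCP (n = 3), where 1 library held 0 counts. The transduced cells held 65.7 ± 23.1 CPM with GFP alone (n = 3) and 375.8 ± 24.8 with NFIL3 (n = 3), a difference of 2.52 ± 0.92 on the log2 scale that did not pass over all genes (adjusted p = 0.298). Retroviral and endogenous Nfil3 reads cannot be told apart in the counts. Nfil3 rose by 4.00 ± 0.68 from ALP to sEILP (adjusted p = 0.00211). The differences from sEILP to cEILP (-1.74 ± 0.66, adjusted p = 0.355), from cEILP to ILCP (-2.51 ± 0.92, 0.194), of GFP from ALP (1.49 ± 0.90, 0.497) and of NFIL3 from cEILP (1.53 ± 0.89, 0.448) did not pass.

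**Figure D1:**
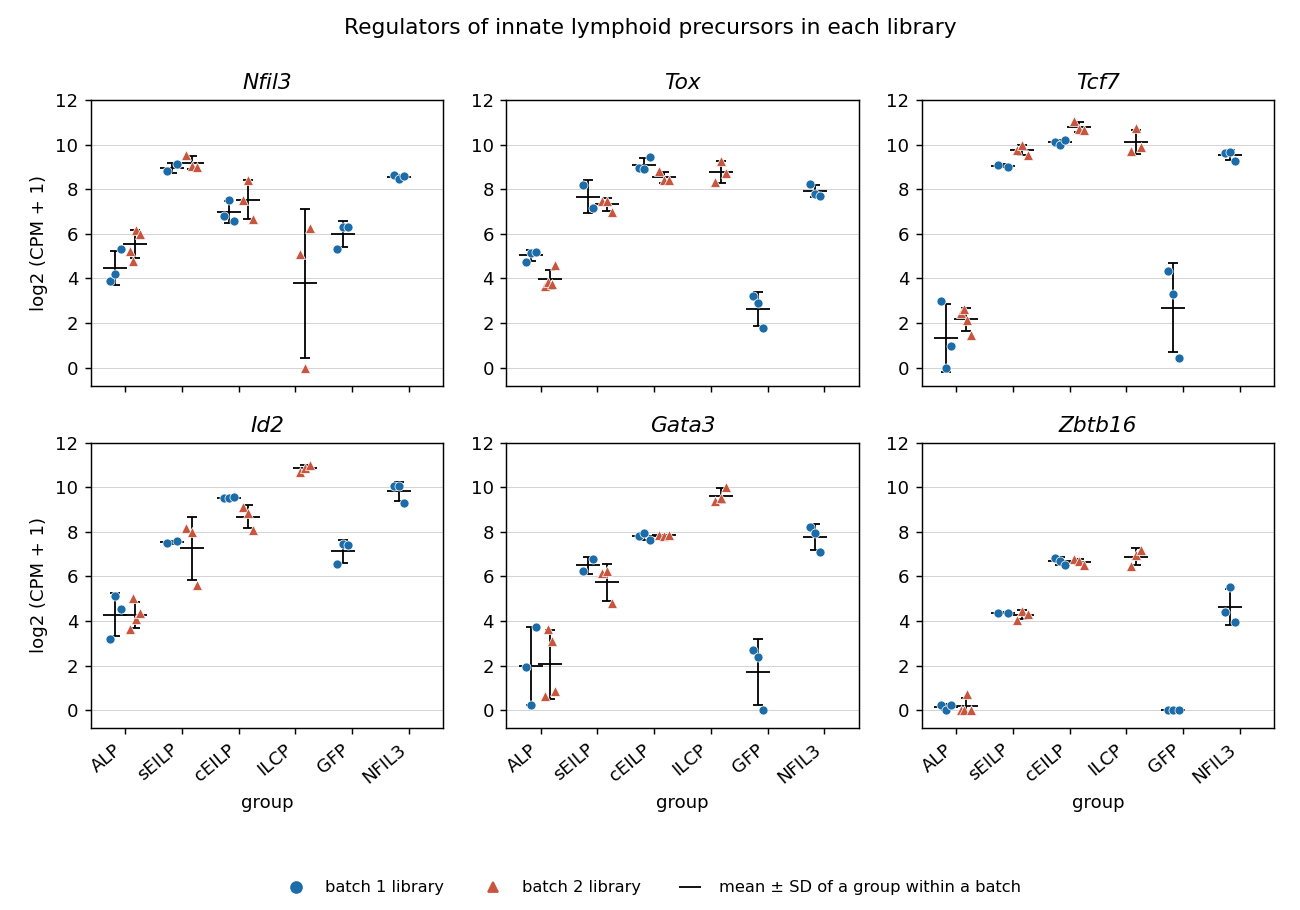
Each point is a library and shows log2(CPM + 1) of Nfil3, Tox, Tcf7, Id2, Gata3 and Zbtb16 by group (circles batch 1, triangles batch 2), with black bars for the mean ± SD of a group within a batch. Tcf7 stood at 743.7 ± 103.6 CPM in NFIL3, 9.48 ± 9.51 in GFP and 3.25 ± 2.50 in ALP.

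The comparison of NFIL3 with GFP asks what forced NFIL3 changed in cultured ALP. Transcription factors that build ILC precursors were among the genes that rose. Tcf7 (ENSMUSG00000000782), which encodes TCF-1, rose from 9.48 ± 9.51 to 743.7 ± 103.6 CPM (log2 fold change 6.33 ± 0.92, adjusted p = 0.000374). Tox (ENSMUSG00000041272), a nuclear factor needed for early ILC progenitors, rose from 5.74 ± 2.99 to 244.9 ± 49.6 (5.44 ± 0.43, 1.55e-07). Zbtb16 (ENSMUSG00000066687), which encodes PLZF and marks ILC precursors, was at 26.9 ± 16.5 CPM against 0 counts, at least 66.4-fold higher (0.000363). Id2 (ENSMUSG00000020644), the inhibitor of E proteins, rose from 144.1 ± 45.4 to 921.6 ± 252.3 (2.68 ± 0.52, 0.00665). Gata3 (ENSMUSG00000015619) rose from 3.25 ± 2.87 to 225.9 ± 82.5 (6.19 ± 1.22, 0.00818), with n = 3 in each group. Of 18 ILC precursor regulators, 7 rose, these and Runx3 (2.31 ± 0.40, 0.00230) and Ets1 (3.52 ± 0.84, 0.0413), and 11 did not pass. Adjusted over the list alone 14 rose, the median was 4.19 and the list ranked higher (camera adjusted p = 8.06e-25, and 0.000193 with an estimated correlation). Id2 did not pass without GFP replicate 1 (adjusted p = 0.061). Ets1 did not pass without any library but NFIL3 replicate 3 (up to 0.1996, without GFP replicate 2). Tox and Ets1 had fallen from ALP to GFP, so their rise over GFP is not by itself the rise over ALP.

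Receptor and lineage lists ranked higher as well. Of 20 ILC precursor surface and signalling genes 2 rose (12 over the list alone, median 3.68, adjusted p = 3.27e-13, and 0.000684 with an estimated correlation): Il2rb, the IL-2 and IL-15 receptor beta chain, from 16.4 ± 13.9 to 1403 ± 299.4 CPM (6.40 ± 1.14, adjusted p = 0.00305), and Cd7 (4.40 ± 0.99, 0.0264). Of 20 NK and cytotoxic genes 2 rose (12 over the list alone, median 4.35 with genes at 0 in a group taken at their bound; 2.55e-14, and 0.000225 with an estimated correlation), Il2rb and the granule membrane gene Nkg7 (2.38 ± 0.29, 6.30e-05). Of 12 ILC2 genes 3 rose (8 over the list alone, median 6.58, or 3.57 at the bound; 8.52e-09, and 0.000684), namely Gata3, Rxrg (at least 42.7-fold, 0.0386) and Hes1 (0.00529). Of 17 T lineage genes 3 rose and 1 fell (6 and 1 over the list alone, median 2.2; 5.66e-05, and 0.000856). These were the kinase gene Lck (2.93 ± 0.32, 1.39e-05), Cd27 (1.73 ± 0.32, 0.00461) and Themis (at least 51.3-fold, 0.0345). From ALP to GFP that list ranked lower and Lck and Cd27 fell, Cd27 by more than it rose here. Rises over GFP are thus not by themselves gains over ALP. Cd6 was at 0 counts and at least 22.2-fold lower (0.000666). Cpa3, a mast cell protease gene, was the only riser of 9 mast cell and basophil genes (4.84 ± 0.94, 0.00716). That list's median was -0.88 and its mean -2.15 while its test ranked it higher (0.595). Single libraries ended several calls. Themis failed without any of the 6 (adjusted p up to 0.131). Rxrg and Cd7 failed without any but NFIL3 replicate 3 (up to 0.136 and 0.132). Each p was highest without GFP replicate 3.

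Single progenitor genes fell. Of 20 multipotent and lymphoid progenitor genes 2 fell, the stem and progenitor antigens Cd34 (-1.70 ± 0.38, adjusted p = 0.0236) and Cd93 (-2.0 ± 0.41, 0.0131). Over the list alone 3 rose and 4 fell, and the median of -0.64 and the lower rank (adjusted p = 0.00723, lost at adjusted p = 0.0834 with an estimated correlation) stood beside a mean of 0.12. Of 17 B lineage genes 1 fell (3 over the list alone, median -2.59, or -2.23 at the bound; 0.00326, lost at adjusted p = 0.0834 with an estimated correlation): Dntt, which encodes the terminal transferase of antigen receptor rearrangement, from 162.4 ± 61.8 to 3.19 ± 2.94 CPM (-5.67 ± 1.33, 0.0357). The lists for myeloid genes (0 of 18 passed; median -0.66; 0.000674), cell cycle (0 of 22; -0.19; 0.0377) and glycolysis (0 of 15; -0.21; 0.0133) ranked lower, lost at adjusted p = 0.138, 0.375 and 0.301 with an estimated correlation. ILC3 and LTi genes (0 of 13, 1 over the list alone, 2.06; 0.00213) and Notch targets (2 of 7, Hes1 and Tcf7; 0.73; 0.0327) ranked higher, lost at 0.0834 and 0.107 as adjusted p with an estimated correlation. Cd34 did not pass without GFP replicate 1 or 2 or NFIL3 replicate 1 or 2 (adjusted p up to 0.160, without NFIL3 replicate 1), Cd93 without GFP replicate 3 or NFIL3 replicate 2 (up to 0.0977, without NFIL3 replicate 2). Dntt did not pass without any library but GFP replicate 3 (up to 0.193, without NFIL3 replicate 1).

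Of the other lists in NFIL3 against GFP only the sort genes passed. Of 15 dendritic and plasmacytoid genes 0 passed (4 higher and 3 lower over the list alone, median 0.00, mean -0.96, adjusted p = 0.726), as did 0 of 15 erythroid and megakaryocyte genes (2 higher over the list alone, 0.00, mean 0.21, 0.398) and 0 of 11 stromal genes (0.00, mean 1.37, 0.688). Of the stromal genes, Vcam1 held 209 counts against 1 (ratio 263.4, 46.8 to 10454; 0.479). Circadian and D-box genes, bound by the family of NFIL3, had 0 of 16 pass (1 over the list alone, 1.78, 0.150). Of 6 E and Id protein genes Id2 rose (0.16, 0.274). Of 15 immediate early and stress genes Btg2 rose (1.99 ± 0.45, 0.0281; list median 0.12, 0.360). Interferon stimulated genes had 0 of 16 pass, with a median of 0.20 and a mean of 0.34 while the test ranked them lower (0.360). Ifit1 held 233 counts against 2 (ratio 146.8, 40.2 to 1220; 0.507), Ifit3, which did not pass either, 27 against 1 (34.0, 5.61 to 1393) and Oas1a 214 against 1572 (-2.46 ± 1.19, 0.492). Of 16 cholesterol synthesis genes 0 passed (0.05, mean -0.01, 0.906). The 9 sort genes ranked higher (2.28e-08, and 0.000225 with an estimated correlation; 3 rose and over the list alone 6 rose and 1 fell). Besides Tcf7 and Zbtb16, these included Kit, the stem cell factor receptor (1.97 ± 0.45, 0.0287). Flt3 was at 7.86 ± 4.44 against 122.7 ± 19.7 CPM (-3.98 ± 1.01) and did not pass (0.0587). The same held for Itga4 (0.84 ± 0.22, 0.0746), Itgb7 (1.88 ± 0.52, 0.0901), Cd244a (0.424), Il7r (0.808) or Thy1 (0.868). The list of MHC class I presentation genes, added after the values were seen, had 6 of 14 rise (8 over the list alone, median 1.08, p = 4.73e-18, and 4.86e-05 with an estimated correlation), with B2m at 1.1 ± 0.18 (0.00104) and H2-K1 at 1.35 ± 0.14 (5.58e-06). Btg2 did not pass without GFP replicate 1 or 2 or NFIL3 replicate 1 or 2 (up to 0.117, without GFP replicate 2). Kit failed without any but GFP replicate 1 (up to 0.113, without GFP replicate 3). It had fallen by more from ALP to GFP, so this rise is not by itself a gain over ALP.

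In NFIL3 against GFP 182 genes passed, 141 higher and 41 lower, of which 150 differed by at least 1 on the log2 scale, and 1587 had an unadjusted p under 0.05. Limma-voom called 255 genes, which held 70 of the 182. Besides Zbtb16, Themis, Rxrg and Hes1, the largest rises included those of Spon2 (at least 59.1-fold, 0.00565), Tgfbr2 and Txk. Tgfbr2, a TGF-beta receptor, held 1533 against 1 count (ratio 1932 with a counting interval from 346.3 to 76370; 0.000175) and Txk 830 against 1 (ratio 1046, 187.3 to 41371; 0.0265). Hes1 held 814 against 2 counts (ratio 513, 141.6 to 4243). The largest falls, besides Dntt, were in Vill (at least 28.4-fold lower, 0.0239), Afap1l1 (1 against 424 counts, ratio 336.4, 60.1 to 13317; 0.0460), Slc8b1 (-7.40 ± 1.26, 0.00205), Golm2 (-6.16 ± 1.37, 0.0241), Osbpl1a (-5.73 ± 1.39, 0.0442), Egfl7 (-2.78 ± 0.37, 0.000141) and Adgrg1 (-2.06 ± 0.43, 0.0155). Of 32 named genes that passed, 17 passed without every library in turn. Afap1l1 failed without any library (up to 0.213), Osbpl1a without any but NFIL3 replicate 3 (up to 0.209). The calls were also lost for Golm2 without GFP replicate 1 or NFIL3 replicate 1 or 2 (up to 0.150), Vill without any NFIL3 library (up to 0.106) and Adgrg1 without GFP replicate 1 or 3 or NFIL3 replicate 1 or 3 (up to 0.0935), each highest without NFIL3 replicate 1. Txk failed without any GFP library or NFIL3 replicate 2 (up to 0.126, without GFP replicate 2). The count fell to 116 and 119 without GFP replicates 1 and 2 and to 114 and 108 without NFIL3 replicates 1 and 2, and was 331 without the 3 libraries with the fewest genes. The authors' deposited table called 219 genes (159 higher, 60 lower), and 80 of the 182 were among them, each with the same sign. All 3 NFIL3 libraries held both Xist and Y-linked transcripts, while 1 GFP library held Xist alone and 2 Y-linked transcripts alone.

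The next question was whether the genes changed by forced NFIL3 were those that change along the path in the animal. They overlapped in the direction of the path. Of the 100 genes most raised from ALP to cEILP in batch 2, 90 were above 0 in NFIL3 against GFP and 39 passed as higher, with a median log2 fold change of 1.61. The 74 lowered genes had a median of -0.39, with 52 below 0, 8 that passed as lower and 3 as higher. The raised and lowered sEILP signatures (34 and 22 genes) had medians of 1.45 and -0.14, with 19 passing as higher in the raised set and 4 lower and 1 higher in the lowered set. The ILCP signatures (100 and 100 genes) had medians of 1.04 and -0.67, with 35 passing as higher and 11 as lower. Camera ranked the raised sets higher (adjusted p = 2.50e-48 for sEILP, 2.50e-66 for cEILP, 1.13e-54 for ILCP) and the lowered sets lower (3.17e-05, 3.61e-10, 4.59e-19), and all 6 calls held with an estimated correlation (adjusted p at most 0.00221). Tox, Tcf7, Id2, Gata3, Zbtb16 and Il2rb rose in NFIL3 against GFP and in cEILP against ALP.

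Over 15568 genes the log2 fold changes of NFIL3 against GFP and of cEILP against ALP, which share no library, had Pearson's r of 0.19 and Spearman's rho of 0.19 across genes, which are not independent replicates. Genes raised in both numbered 69, against 2.89 by the product of the shares, and genes lowered in both 17 (1.01). The 4 genes that moved in opposite directions were Fxyd5, Ifngr1, Cd53 and Tgtp2 (4.3 by the product of the shares). Of 701 genes that passed in cEILP against ALP, 521 (74.3%) had the same sign in NFIL3 against GFP. On the score of cEILP signature genes, ALP of batch 1 stood at -3.58 ± 0.11 (n = 3), GFP at -2.63 ± 0.12 (n = 3), sEILP at -0.64 ± 0.15 (n = 2), NFIL3 at 0.22 ± 0.44 (n = 3) and cEILP at 1.35 ± 0.21 (n = 3). NFIL3 was 2.85 above GFP (two-sided exact permutation p = 0.1) and 1.13 below cEILP (exact permutation p = 0.1). GFP was 0.95 above ALP (exact permutation p = 0.1), and 0.1 is the smallest p that 3 against 3 libraries allow.

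**Figure D2:**
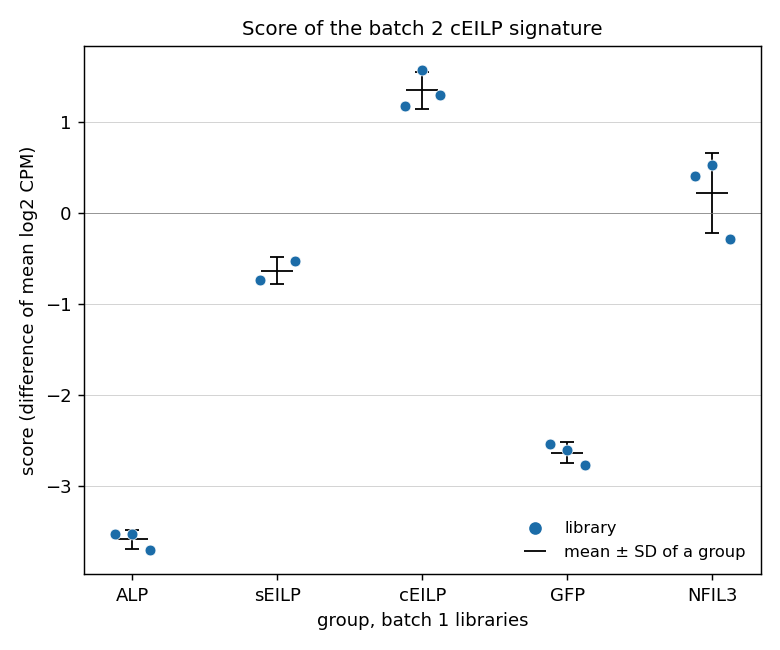
The score of each batch 1 library, in log2 CPM of genes raised from ALP to cEILP in batch 2 minus those lowered, is plotted by group with the mean ± SD. The NFIL3 libraries, at 0.22 ± 0.44, lie above every GFP library and below every cEILP library.

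The comparison of sEILP with ALP follows specification to the ILC lineage in the animal. Along with Nfil3, several of the same regulators rose. Tcf7 rose from 3.25 ± 2.50 (n = 7) to 736.0 ± 210.0 CPM (n = 5; log2 fold change 7.81 ± 0.69, adjusted p = 3.13e-07; 7.74 in batch 1 and 7.88 in batch 2). Tox rose by 3.08 ± 0.27 (3.02e-07), Id2 by 3.22 ± 0.37 (1.30e-05), Gata3 by 3.79 ± 0.74 (0.00856) and Runx3 by 1.78 ± 0.28 (0.000692). Zbtb16 reached 18.9 ± 2.03 CPM (6.89 ± 0.80, 3.10e-05; 7.17 and 6.62 within batches). Tox2 held 937 against 2 counts (ratio 613.8, 169.5 to 5076; 0.00416), although single libraries of the groups overlapped and it did not pass without sEILP replicate 2 of batch 2 (0.255). Of 18 ILC precursor regulators 8 rose and 10 did not pass (11 rose and 2 fell over the list alone, median 3.15; 1.08e-18, and 0.000806 with an estimated correlation). Cpa3 rose from 7.37 ± 4.74 to 814.1 ± 204.3 CPM (6.77 ± 0.72, 4.81e-06), the only riser of 9 mast cell and basophil genes (3 over the list alone, 0.91; 5.91e-05, and 0.0406). Il2rb rose by 6.47 ± 0.85 (7.89e-05; 8.27 and 4.67 within batches).

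Surface and signalling genes ranked higher and cell cycle and B lineage genes lower in sEILP against ALP. Of 20 surface and signalling genes 4 rose (7 rose and 1 fell over the list alone, median 2.06, or 1.72 at the bound; 2.54e-05, and 0.0412 with an estimated correlation), Il2rb, Cd7 (2.93 ± 0.65, 0.0217) and the gate genes Itga4 (131.9 ± 53.4 to 682.2 ± 226.2 CPM, 2.39 ± 0.16, 1.49e-08) and Itgb7 (3.08 ± 0.38, 3.24e-05). The sort genes as a list ranked higher (camera adjusted p = 4.39e-10, and 8.83e-05 with an estimated correlation). Of these, 4 of 9 rose (4 rose and 2 fell over the list alone, median 0.31). They are the markers of the gates, so the sort itself bears on this rank and the p-values measure no separate effect. Flt3 (-1.60 ± 0.68, 0.326), Il7r (-2.06 ± 0.65, 0.145), Kit (0.896), Thy1 (0.912) and Cd244a (0.994) did not pass. NK and cytotoxic genes ranked higher with Il2rb the only riser of 20 (7 over the list alone, 0.84; 4.62e-07, and 0.0150). Of 22 cell cycle genes 6 fell (9 over the list alone, -0.54; 1.80e-07, and 0.0406), such as the survivin gene Birc5 (-1.12 ± 0.20, 0.00410), the mitotic kinase gene Cdk1 (-1.05 ± 0.20, 0.00759), Ccnb1 (-0.94 ± 0.20, 0.0158) and Ccnb2 (-0.95 ± 0.22, 0.0242). Of 20 multipotent progenitor genes 2 fell (1 rose and 6 fell over the list alone, -0.81; 0.00211, and 0.04998), Ccr9 and the E protein gene Tcf4 (-1.64 ± 0.35, 0.0177). Of 17 B lineage genes the B cell adaptor Blnk fell (134.7 ± 91.0 to 0.689 ± 1.5 CPM, -9.93 ± 1.92, 0.00985; 4 over the list alone, -2.34, or -1.20 at the bound; 0.00126, and 0.04998). Blnk failed without sEILP replicate 1 or 2 of batch 1 (up to 0.0978). Leaving out replicate 1 ended Cdk1 (0.0735), and replicate 2 ended Ccnb1 (0.12) and Birc5 (0.0501). Ccnb2 failed without ALP replicate 3 or sEILP replicate 1 or 2 of batch 1, or ALP replicate 4 or sEILP replicate 2 of batch 2 (up to 0.125, without sEILP replicate 2 of batch 1). Tcf4 failed without sEILP replicate 1 or 2 of batch 1 or replicate 1 of batch 2 (up to 0.130, without replicate 2 of batch 1). Cd7 failed without ALP replicate 2 or 3 or sEILP replicate 2 of batch 1 or sEILP replicate 1 of batch 2 (up to 0.0776, without ALP replicate 3 of batch 1).

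Interferon and metabolic lists were also read in sEILP against ALP. Of 16 interferon stimulated genes 0 passed (1 fell over the list alone), yet the list ranked lower (median -2.14, adjusted p = 2.54e-05, and 0.0406 with an estimated correlation). Glycolysis genes ranked higher, and 3 of 15 rose (3 over the list alone, 0.17; 0.00383, lost at adjusted p = 0.210 with an estimated correlation): Pfkp (1.12 ± 0.21, 0.00462), Aldoa (0.67 ± 0.13, 0.00816) and Pgam1 (0.75 ± 0.15, 0.0106). Notch targets had a median of -0.15 and a mean of 0.42 while the test ranked them higher (0.0343, lost at adjusted p = 0.119 with an estimated correlation), with Tcf7 the only riser of 7 (2 rose and 1 fell over the list alone). Pgam1 did not pass without sEILP replicate 2 of batch 1 (0.0789). The other 11 lists did not pass.

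In sEILP against ALP 197 genes passed (110 higher, 87 lower; 144 with a log2 fold change of at least 1; 1989 at an unadjusted p under 0.05), against a median of -0.13 over all genes. The larger share was lower under other settings, with 332 higher and 809 lower by DESeq2, 105 and 357 by limma-voom (292 and 508 with quality weights), 118 and 189 with only the compared libraries and 150 and 159 without the 3 libraries with the fewest genes. Besides Tcf7, Zbtb16, Cpa3 and Il2rb, the largest rises were in Fgf3, a fibroblast growth factor gene (1522 against 3 counts, ratio 664.7, 227.0 to 3227; 1.30e-05), Mdga1 (8.23 ± 1.47, 0.00468), Ahsg (7.97 ± 1.66, 0.0158) and Asb1 (7.80 ± 1.68, 0.0201). The largest falls, besides Blnk, were in the chemokine receptor gene Ccr9 (at least 95.6-fold lower, 0.0273), Rasgrp3 (at least 65.6-fold, 0.0454), Epha2 (at least 60.1-fold, 0.0177), Rgs8 (at least 45.5-fold, 0.0179), Robo4 (at least 40.6-fold, 0.0235), Paqr5 (-8.28 ± 1.48, 0.00472; -3.76 and -12.79 within batches) and Rgl1 (-8.12 ± 1.94, 0.0371). Of the 197, 194 had the same sign in both batches. Pde3b and 0610030E20Rik differed between batches, both named after their values were seen. Folds within batches were fitted without a floor, so large ones are inexact. In the shared fit, batch 1 alone called 41 genes and batch 2 alone 61. Without the 3 libraries with the fewest genes 309 passed, and the authors' deposited table called 329 (122 higher, 207 lower), sharing 133. Of 32 named genes that passed, 15 passed without every library in turn. Rasgrp3 failed without any of the 12 libraries (up to 0.206) and Rgl1 without any ALP library or sEILP replicate 1 or 2 of batch 1 (up to 0.271). The calls were lost for Rgs8 and Epha2 without sEILP replicate 1 or 2 of batch 1 (up to 0.0865 and 0.0978), Ccr9 without these or ALP replicate 3 (up to 0.168) and Robo4 without these or ALP replicate 1 or 3 (up to 0.121), each highest without sEILP replicate 1 of batch 1. Ahsg and Asb1 failed without any ALP library of batch 1 (up to 0.0703 and 0.0816). In batch 2 the Zbtb16 reporter was present in sEILP and absent in ALP, and 3 of 4 ALP libraries of that batch held Xist alone while no sEILP library did.

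The comparison of cEILP with sEILP follows commitment. The ILC and T cell regulator Bcl11b, the nuclear receptor gene Rora and Tox rose. Bcl11b was at 31.3 ± 24.5 CPM in cEILP (n = 6) and held 1 count in sEILP (n = 5) against 1867 (ratio 1761, 315.6 to 69574; adjusted p = 0.0186). Rora rose from 11.6 ± 9.24 to 262.2 ± 111.5 CPM (4.62 ± 0.91, 0.0185; 5.27 and 3.98 within batches) and Tox from 183.0 ± 63.6 to 464.6 ± 129.1 (1.29 ± 0.27, 0.0318). Of 18 regulators these 3 rose and 15 did not pass (8 rose and 1 fell over the list alone, median 1.95; 3.70e-11, and 0.00524 with an estimated correlation). Among the genes that did not pass, Tcf7 stood at 1458 against 736.0 CPM (0.556) and the gate gene Zbtb16 at 101.6 ± 9.02 against 18.9 ± 2.03 (2.42 ± 0.70, 0.188). Of 12 ILC2 genes 2 rose, Rora and Rxrg (4 over the list alone, 1.63, or 1.43 at the bound; 6.75e-06, and 0.00682). Multipotent progenitor genes ranked lower, with 2 of 20 fallen (6 over the list alone, -0.83; 4.04e-08, and 0.00524), the myeloid and dendritic regulator Irf8 (1134 ± 372.0 to 341.0 ± 220.5 CPM, -1.77 ± 0.38, 0.0318) and Mef2c (-1.29 ± 0.29, 0.0494). Cell cycle genes ranked lower (5.87e-12, and 0.00768) with 0 of 22 passed over all genes and 9 over the list alone (-0.42). The dendritic list ranked lower (median -0.31, mean 0.03; 0.0225, lost at adjusted p = 0.385 with an estimated correlation), with Irf8 fallen of 15 (2 over the list alone). Without sEILP replicate 1 or 2 of batch 1, Bcl11b and Rora did not pass (up to 0.145 each). Irf8 failed without any library but sEILP replicates 2 and 3 and cEILP replicate 2 of batch 2 (up to 0.103, without cEILP replicate 1 of batch 2). Mef2c failed without any but cEILP replicate 1 of batch 1 and sEILP replicate 3 of batch 2 (up to 0.153, without cEILP replicate 3 of batch 2). Tox failed without sEILP replicate 2 or cEILP replicate 3 of batch 1, or sEILP replicate 1 or 3 or cEILP replicate 1 or 3 of batch 2 (up to 0.190, without sEILP replicate 2 of batch 1). Rxrg failed without any but sEILP replicates 2 and 3 of batch 2 (up to 0.209, without sEILP replicate 1 of batch 1).

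In cEILP against sEILP 71 genes passed (32 higher, 39 lower; 56 with a log2 fold change of at least 1; 1556 at an unadjusted p under 0.05). The larger share was higher by DESeq2 (497 and 302 lower) and limma-voom (102 and 51, or 160 and 115 with quality weights), with only the compared libraries (47 and 42) and without sEILP replicate 1 (31 and 28) or 2 (36 and 28) of batch 1. Batch 1 alone called 28 genes, and batch 2 alone 0 by edgeR, with 852 at an unadjusted p under 0.05, while 70 of the 71 had the same sign in both batches. Besides Bcl11b and Rora, the largest rises included those of Rxrg (7.67 ± 1.55, 0.0494; 11.99 and 3.35 within batches), Themis (7.32 ± 1.57, 0.0494; 10.21 and 4.44), Abcb9 (6.49 ± 1.34, 0.0305; 11.56 and 1.41), Tnfrsf9 (6.38 ± 1.34, 0.0318; 10.87 and 1.88) and Pde3b (4.94 ± 0.58, 0.000387; 9.10 and 0.77). The largest falls, besides Irf8, were in Klhl18 (-5.90 ± 0.93, 0.00529; -11.2 and -0.61), the IL-1 receptor gene Il1r1 (-5.77 ± 0.96, 0.00539; -9.98 and -1.56), Cfp (-2.29 ± 0.34, 0.00353; -2.89 and -1.69), Ifngr2 (-2.19 ± 0.46, 0.0305), Unc93b1 (-1.99 ± 0.26, 0.00112; -2.64 and -1.34), Ccnf (-1.87 ± 0.36, 0.0173) and Parp8 (-1.44 ± 0.29, 0.0189). Cd6 fell by 3.98 ± 0.73 (0.0139; -7.36 and -0.60). The change differed between batches in 5 genes, Pde3b, Klhl18, Arhgef18, Mia2 and 0610030E20Rik, the last 3 named after their values were seen. Folds here were fitted without a floor, so large ones are inexact.

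The calls of cEILP against sEILP leaned on single libraries. Without sEILP replicate 1, cEILP replicate 1 or cEILP replicate 3 of batch 2 the count fell to 40, 32 and 37, and without the 3 libraries with the fewest genes it was 129. The sEILP library of batch 1, replicate 2, enters the cEILP mean in the authors' deposited table, and counted as cEILP it gave 24 genes, 1 of them among the 71. Of 19 named genes that passed, only Pde3b, Klhl18, Il1r1, Cfp and Unc93b1 passed without every library in turn. Leaving out either sEILP library of batch 1 ended the calls of Rxrg, Themis, Abcb9, Tnfrsf9 and Ifngr2, and leaving out replicate 1 ended Parp8. Leaving out cEILP replicate 1 or 3 of batch 2 ended each of these and Ccnf and Cd6. Replicate 2 of the same group ended Rxrg, Themis and Tnfrsf9. Without sEILP replicate 1 of batch 2, Rxrg, Abcb9, Tnfrsf9, Ifngr2 and Ccnf failed. Any cEILP library of batch 1 ended Rxrg and Themis, and replicate 1 or 2 ended Ifngr2. The highest adjusted p came without sEILP replicate 1 of batch 1 for Rxrg (0.209), Abcb9 (0.172), Tnfrsf9 (0.172) and Parp8 (0.0819) and without its replicate 2 for Themis (0.245). It came without cEILP replicate 3 of batch 2 for Ifngr2 (0.0876) and Ccnf (0.0650) and without replicate 1 for Cd6 (0.0549). The gate genes Kit (1.48 ± 0.34, 0.0502), Flt3 (-2.17 ± 0.67, 0.235), Il7r (0.407), Itga4 (0.509), Itgb7 (1.00), Thy1 (1.00) and Cd244a (1.00) did not pass. The other 17 lists did not pass.

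The comparison of ILCP with cEILP, 3 libraries each in batch 2, follows the step to the ILC precursor. Genes for cytokine receptors were among those that rose. Icos, a costimulatory receptor gene, rose from 9.21 ± 5.17 to 1113 ± 277.6 CPM (6.92 ± 1.38, adjusted p = 0.00601), Ltb, which encodes lymphotoxin beta, by 4.78 ± 0.95 (0.00571) and the gate gene Il7r from 126.5 ± 44.4 to 1537 ± 257.5 CPM (3.60 ± 0.90, 0.0318). Il2ra, the IL-2 receptor alpha chain, and the IL-33 receptor gene Il1rl1 were at 0 counts in cEILP and at least 848.6-fold (0.00426) and 1057-fold (0.0458) higher. Of 20 surface and signalling genes 5 rose and 1 fell, Itga4 (-1.49 ± 0.23, 0.000410), with 8 and 1 over the list alone (median 3.33; 1.14e-10, and 0.00255 with an estimated correlation). Of 18 regulators 2 rose (4 rose and 2 fell over the list alone, 1.89; 0.000204, lost at adjusted p = 0.0941 with an estimated correlation), Ets1 (4.01 ± 0.85, 0.00928) and Id2 (2.1 ± 0.51, 0.0241). ILC2 genes (2 of 12 rose, Icos and Il1rl1; 4 over the list alone, 4.34, or 3.42 at the bound; 5.55e-08, and 0.00180), ILC3 and LTi genes (Ltb of 13; 1 over the list alone, 4.78, or 4.50; 2.04e-06, and 0.0173), NK genes (0 of 20, 0 over the list alone, 1.87, or 1.74; 3.12e-05, and 0.0173) and T lineage genes (0 of 17, 0 over the list alone, 1.43; 0.0125, and 0.0342) ranked higher. Leaving out a library ended Il1rl1 in all 6 cases (up to 0.163), Id2 in 5 (all but ILCP replicate 1, up to 0.146), Il7r without any cEILP library or ILCP replicate 3 (up to 0.159) and Ets1 without cEILP replicate 2 or 3 (up to 0.0653), each highest without cEILP replicate 3.

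Progenitor genes ranked lower in ILCP than in cEILP, and single myeloid genes fell. Of 20 multipotent progenitor genes 9 fell and 1, Ccr9, rose (10 and 1 over the list alone, median -1.96; 4.15e-10, and 0.00180 with an estimated correlation). Cd34 fell from 524.6 ± 151.8 to 46.0 ± 37.2 CPM (-3.51 ± 0.40, 1.21e-05), Bcl11a by 2.42 ± 0.42 (0.00161), Mef2c by 2.2 ± 0.41 (0.00324), Irf8 by 2.64 ± 0.53 (0.00634) and Flt3 by 4.95 ± 1.05 (0.00949). Of 18 myeloid genes 2 fell, Cd68 (at least 42.8-fold, 7.44e-06) and Csf3r (at least 178.0-fold, 0.0146), with 3 over the list alone (-1.98, or -1.72 at the bound; 5.62e-05, lost at adjusted p = 0.126 with an estimated correlation). Glycolysis genes ranked higher with 2 of 15 risen (3 over the list alone, 0.39; 0.00174, lost at adjusted p = 0.211 with an estimated correlation), Pkm (1.16 ± 0.20, 0.00174) and Eno1 (0.88 ± 0.18, 0.00637). In lists that did not pass, Cd74, the MHC class II invariant chain, rose (3.99 ± 0.79, 0.00576), and so did the mitotic genes Ccnb2 (1.27 ± 0.29, 0.0177) and Cdc20 (1.08 ± 0.26, 0.0271). The replication licensing genes Mcm7 (-0.87 ± 0.17, 0.00644) and Mcm6 (-0.60 ± 0.15, 0.0345) fell, as did the stromal marker Pdgfrb (-3.42 ± 0.87, 0.0357), Bst2 (-1.39 ± 0.34, 0.0245) and Ly6d (at least 20.9-fold, 0.0200). Single libraries ended the calls of Irf8 (cEILP replicate 2, 0.0517), Csf3r (ILCP replicates 2 and 3, up to 0.0529), Ly6d (any ILCP library, up to 0.0681), Pdgfrb (any cEILP library or ILCP replicate 1, up to 0.0895), Ccr9 (any cEILP library, up to 0.115), Ccnb2 (any cEILP library or ILCP replicate 1 or 2, up to 0.0916), Mcm6 (any cEILP library or ILCP replicate 2 or 3, up to 0.17), Bst2 (cEILP replicate 1 or 3 or ILCP replicate 2 or 3, up to 0.117) and Cdc20 (cEILP replicate 1 or 2 or ILCP replicate 1 or 2, up to 0.132).

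In ILCP against cEILP 378 genes passed (143 higher, 235 lower; 300 with a log2 fold change of at least 1; 2349 at an unadjusted p under 0.05). The larger share was higher with only the compared libraries (89 and 35 lower) and by limma-voom with quality weights (613 and 500). Besides Il1rl1 and Il2ra, the largest rises were in the scavenger receptor gene Stab2 (at least 2898-fold, 0.00490), Asb2 (at least 494-fold, 0.0403), Pcsk1 (at least 450.3-fold, 0.0418), Syne2 (at least 136.8-fold, 0.0118), Metrnl (at least 113.8-fold, 0.00923) and Ccr9 (12070 counts against 1, ratio 10995, 1973 to 434318; 0.0228). The largest falls, each to 0 counts, were in the platelet integrin gene Itga2b (at least 682.1-fold, 0.0113), Sstr2 (549.8-fold, 0.000133), the granule protease gene Prss57 (418.1-fold, 4.33e-09), Sh2d5 (313.2-fold, 3.64e-08), Ak4 (301.8-fold, 0.0123), Cercam (295.9-fold, 0.000323), Drc7 (286.6-fold, 0.0251) and Clec4e (213.0-fold, 0.00508). The gate gene Thy1 held 1212 against 2 counts (ratio 552, 152.5 to 4563) and did not pass (0.123), nor did Itgb7 (0.609), Kit (0.781), Tcf7 (0.840), Cd244a (0.842) or Zbtb16 (1.00). Of 40 named genes that passed, 23 passed without every library in turn. Asb2 and Pcsk1 failed without any library (up to 0.142 and 0.115), Ccr9 and Syne2 without any cEILP library (up to 0.115 and 0.0551) and Drc7 without cEILP replicate 2 or any ILCP library (up to 0.0791). The count fell to 242, 241 and 225 without cEILP replicates 1, 2 and 3, and was 456 without the 3 libraries with the fewest genes. All 3 ILCP libraries held Xist alone, while of the cEILP libraries of batch 2 1 held Y-linked transcripts alone and 2 held both. The Zbtb16 reporter was present in cEILP and absent in ILCP.

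GFP against ALP, 3 libraries each in batch 1, gives the background against which NFIL3 was read. Culture, virus and sort (GFP and Mac1, not the gates of ALP) differ together. Glycolysis genes ranked higher, and 8 of 15 rose (12 over the list alone, median 1.14; adjusted p = 5.85e-24, and 0.000732 with an estimated correlation). Ldha, lactate dehydrogenase A, rose from 1163 ± 117.7 to 3653 ± 725.1 CPM (1.65 ± 0.15, 1.20e-06), Aldoa by 1.98 ± 0.19 (1.23e-06), Eno1 by 1.67 ± 0.18 (7.75e-06) and Pfkp by 2.25 ± 0.30 (9.97e-05). Cholesterol synthesis genes ranked higher, and 3 of 16 rose (6 over the list alone, 1.47; 1.46e-07, and 0.00162), Fdps (1.96 ± 0.38, 0.00412), Hmgcs1 (1.66 ± 0.38, 0.0172) and Cyp51 (1.63 ± 0.44, 0.0473). Progenitor genes ranked lower, and 4 of 20 fell (8 over the list alone, -1.42; 2.99e-08, and 0.00162), among them Satb1 at -2.87 ± 0.41 (0.000222), Cd34 at -2.08 ± 0.38 (0.00226) and Hlf. Of 17 T lineage genes 2 fell (2 over the list alone, -3.07, or -2.43 at the bound; 0.000301, and 0.00385), Lck (-2.51 ± 0.31, 4.61e-05) and Cd27 (-3.16 ± 0.34, 7.45e-06). The MHC class I list, added after the values were seen, had 7 of 14 fall (10 over the list alone, median -1.07). Hmgcs1 failed without any ALP library or GFP replicate 2 (up to 0.177). Cyp51 failed without any but GFP replicate 1 (up to 0.246, without GFP replicate 3).

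Regulators moved in both directions from ALP to GFP. Tox fell from 32.1 ± 5.37 to 5.74 ± 2.99 CPM (-2.51 ± 0.39, adjusted p = 0.000485), Ets1 fell by 3.33 ± 0.84 (0.0323) and Id2 rose from 21.3 ± 12.7 to 144.1 ± 45.4 CPM (2.76 ± 0.52, 0.00349). The regulator list did not pass. NK genes ranked higher (2 of 20 rose, Fcer1g at 1.91 ± 0.32, 0.00113, and Il2rb; 3 over the list alone, 1.32, or 0.68 at the bound; 0.00699, lost at adjusted p = 0.147 with an estimated correlation), as did myeloid genes (Cebpb rose of 18, 2.06 ± 0.52, 0.0349; 1 over the list alone, 1.64; 8.26e-05, lost at 0.147 as adjusted p with an estimated correlation). Erythroid genes ranked lower (3 of 15 fell and 4 over the list alone, -6.94, or -2.71 at the bound; 6.47e-05, lost at adjusted p = 0.121 with an estimated correlation), namely the carbonic anhydrase genes Car1 and Car2 (-5.41 ± 0.80, 0.000285) and the globin gene Hba-a2. The gate gene Kit fell by 2.50 ± 0.46 (0.00234), and Flt3 (-2.83 ± 0.94, 0.146), Il7r (-2.81 ± 0.88, 0.110), Itgb7 (0.119), Tcf7 (0.371), Zbtb16 (0 against 3 counts, 0.422), Thy1 (0.751), Cd244a (0.878) and Itga4 (0.912) did not pass. In lists that did not pass, Dntt fell from 4527 ± 1295 to 162.4 ± 61.8 CPM (-4.80 ± 1.23, 0.0362), Mcm6 fell (-0.64 ± 0.15, 0.0243) and Pdcd1 rose (410 against 3 counts, ratio 123.1, 41.8 to 599.4; 0.0428). Dntt and Cebpb failed without any of the 6 libraries (up to 0.158 and 0.160). Ets1 failed without any but ALP replicate 2 (up to 0.162), Pdcd1 without any but GFP replicate 3 (up to 0.197). Mcm6 failed without ALP replicate 2 or 3 or GFP replicate 1 or 2 (up to 0.134).

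In GFP against ALP 377 genes passed (154 higher, 223 lower; 304 with a log2 fold change of at least 1; 1918 at an unadjusted p under 0.05). The largest rises were in Emilin2 (5575 counts against 1, ratio 5022, 901.0 to 198396; 0.00793), Tmem51 (at least 27.4-fold, 0.0498), Natd1 (325 against 2, ratio 146.4, 40.2 to 1214; 0.0414), Tnfrsf9 (6.47 ± 1.45, 0.0153) and Il2rb (5.60 ± 1.31, 0.0197). The largest falls were in Car1 (at least 265.3-fold, 0.0442), Shisa8 (at least 211.0-fold, 0.000185), Hba-a2 (1 count against 7894, ratio 8763, 1572 to 346169; 0.0137), Hlf (at least 64.7-fold, 0.0149) and Tspan6 (1 against 2314, ratio 2569, 460.6 to 101505; 0.00679). Of 32 named genes that passed, 16 passed without every library in turn. Tmem51, Natd1 and Car1 failed without any library (up to 0.187, 0.174 and 0.162), Tnfrsf9 without any ALP library (up to 0.0966) and Il2rb without these or GFP replicate 3 (up to 0.0935). Emilin2 failed without ALP replicate 1 or 3 (up to 0.0680), Hba-a2 without ALP replicate 3 or any GFP library (up to 0.150). Hlf failed without any GFP library (up to 0.0781), Tspan6 without GFP replicate 2 (0.0504). The count fell to 227 without ALP replicate 3 and 238 without GFP replicate 2, and was 644 without the 3 libraries with the fewest genes.

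The comparison of NFIL3 with cEILP, 3 libraries each in batch 1, sets the precursors made in culture beside the committed progenitor of the animal. Of 18 regulators 0 passed (2 lower over the list alone, median -0.05, mean 0.27, ranked lower at adjusted p = 0.347). Tcf7 (-0.58, 0.863) and Zbtb16 (-1.93 ± 0.88, 0.367) did not pass, although Zbtb16, at 26.9 ± 16.5 against 102.7 ± 11.3 CPM, was lower in each NFIL3 library than in any cEILP library. Of 15 glycolysis genes 8 were higher in NFIL3 (9 over the list alone, 1.08; 7.71e-15, and 0.00406 with an estimated correlation), such as Eno1 (1.75 ± 0.18, 6.35e-06), Gapdh (1.09 ± 0.15, 0.000241) and Ldha (1.02 ± 0.15, 0.000510). Cholesterol synthesis genes ranked higher (0 of 16, 4 over the list alone, 1.17; 8.66e-06, and 0.00406). Of 22 cell cycle genes 3 were higher (8 over the list alone, 0.44; 5.08e-06, lost at adjusted p = 0.0768 with an estimated correlation), Rrm2 (1.52 ± 0.29, 0.00581), Ccnb2 (1.42 ± 0.29, 0.0109) and Cdc20 (1.05 ± 0.26, 0.0449). Of 15 dendritic genes 3 were higher (6 over the list alone, 0.39; 0.00785, lost at adjusted p = 0.260 with an estimated correlation), Cd74 (45.9 ± 18.5 in cEILP to 1044 ± 448.7 CPM, 4.51 ± 0.81, 0.00307), H2-Ab1 (3.44 ± 0.62, 0.00307) and the chemokine receptor gene Ccr7 (3.78 ± 0.72, 0.00585). Of 20 NK genes the chemokine gene Xcl1 was higher (14 over the list alone, 3.24; 4.84e-09, and 0.00406). Ccnb2 failed without NFIL3 replicate 3 (0.0834) and Cdc20 without cEILP replicate 1 or 2 or NFIL3 replicate 1 or 3 (up to 0.161).

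Other lists split between the groups. ILC3 and LTi genes ranked higher in NFIL3 (1 of 13 and 3 over the list alone, median 2.52, or 2.01 at the bound; adjusted p = 0.00271, lost at adjusted p = 0.1 with an estimated correlation) with Il1r1 at 841 against 2 counts (ratio 466.1, 128.6 to 3855; 0.00307). Surface and signalling genes ranked higher although the only gene that passed was lower, Itga4 (-0.90 ± 0.22, 0.0446; 2 higher and 1 lower over the list alone, 2.79; 0.00464, lost at adjusted p = 0.161 with an estimated correlation). Erythroid genes ranked lower (0 of 15, 0 over the list alone, -7.11, or -2.44; 1.80e-05, lost at adjusted p = 0.0686 with an estimated correlation), as did the sort genes (2 of 9 lower, Itga4 and Kit at -1.88 ± 0.45, 0.0299; 3 over the list alone, -0.90; 0.00464, and 0.0400). The other gate genes, Flt3 (0.250), Il7r (0.326), Thy1 (0.454), Itgb7 (0.737) and Cd244a (0.920), did not pass. The cEILP were gated by such markers and the NFIL3 cells by GFP and Mac1, so the sort bears on this rank too. In lists that did not pass, Cd34 (-2.30 ± 0.38, 0.00157) and Dntt (-6.68 ± 1.39, 0.0114) were lower. Itga4 and Kit failed without any library but cEILP replicate 2 (up to 0.191 and 0.140), and Dntt without NFIL3 replicate 1 or 2 (up to 0.0815).

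Between NFIL3 and cEILP 237 genes passed (140 higher, 97 lower; 199 with a log2 fold change of at least 1; 2022 at an unadjusted p under 0.05). The largest rises were in Galnt3 (at least 119.8-fold, 0.0415), Nt5e, the ecto-nucleotidase CD73 (at least 95.9-fold, 0.0270), Metrnl (at least 93.9-fold, 0.0141), Ctnnd2 (at least 88.4-fold, 0.0340) and Xcl1 (3217 counts against 1, ratio 3566, 639.5 to 140878; 0.0415). The largest falls were in Sstr2 (at least 222.9-fold, 0.000492), Armcx1 (at least 119.2-fold, 0.0105), Slc27a2 (at least 64.6-fold, 0.0237), Mdga1 (1 count against 2235, ratio 2016, 361.5 to 79682; 0.0141) and the angiopoietin gene Angpt1 (2 against 3621, ratio 1633, 451.9 to 13493; 5.11e-07). Kdm5d, on the Y chromosome, held 1 against 1320 counts (ratio 1191, 213.4 to 47075; 0.0480). Of 25 named genes that passed, 12 passed without every library in turn. Galnt3, Xcl1 and Kdm5d failed without any library (up to 0.1195, 0.139 and 0.190), Ctnnd2 without any but NFIL3 replicate 1 (up to 0.112). The calls were also lost for Nt5e without any cEILP library or NFIL3 replicate 1 (up to 0.0891), Metrnl without cEILP replicate 1 or 3 (up to 0.0571), Armcx1 without NFIL3 replicate 2 (0.0522), Mdga1 without any NFIL3 library (up to 0.0891) and Slc27a2 without these or cEILP replicate 3 (up to 0.102). The count fell to 150 without NFIL3 replicate 2 and was 349 without the 3 libraries with the fewest genes. The NFIL3 cells were cultured and the cEILP were not, so culture and origin differ together. They grew on stroma, and 0 of 11 stromal genes passed (median 5.39, or 2.38 at the bound, mean 2.87, 0.644). Cxcl12 held 1057 counts against 2 (ratio 585.8, 161.8 to 4843; 0.270), Sparc 409 against 2 (226.7, 62.4 to 1878; 0.384) and Acta2 48 against 1 (53.2, 9.10 to 2145; 0.422), while Pdgfrb was lower (-2.46 ± 0.85, 0.182).

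**Figure D3:**
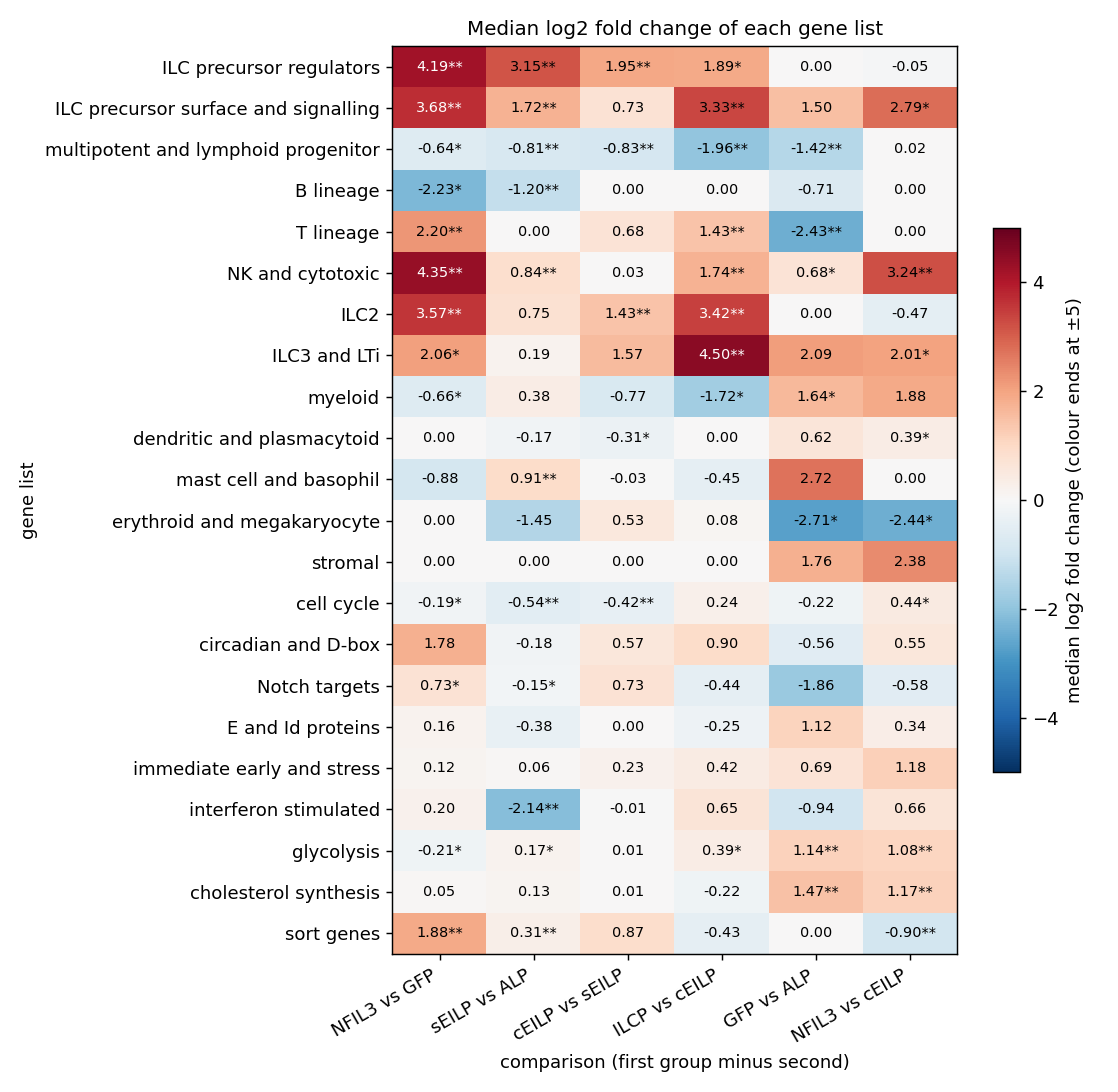
The median log2 fold change of each of the 22 lists in the 6 comparisons is shown by colour, with genes at 0 counts in a group taken at their bound. A single star marks lists that passed camera with the preset correlation only and a double star those that passed with an estimated correlation too, whatever the sign of the median. The regulator list stands at 4.19 in NFIL3 against GFP and at -0.05 in NFIL3 against cEILP.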

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

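The rules that picked the values in this part were fixed before the data were examined, and both tests of the lower batch 2 count below were chosen before their outcome was seen, whereas the alternative without 3 libraries on which the first of them rests was chosen after the data were seen.

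The transcript of the forced factor stood out in a cEILP library. Nfil3 reached 339.2 CPM in cEILP replicate 2 of batch 2, against 184.6 in the next of the 6 cEILP libraries and 95.7 in the lowest. The same library held Flt3, a cytokine receptor gene that fell from ALP to cEILP, at 283.3 CPM, against 118.6 in the next and 25.5 in the lowest. Single sEILP libraries held Nfil3 at 447.5 to 737.8 and Flt3 at 160.8 to 740.3 CPM. Il7r, the IL-7 receptor gene, reached 459.5 CPM in ALP replicate 2 of batch 2, with the next of the 7 ALP libraries at 252.8 and the lowest at 107.1. The other 3 values lay near the floor of 3 counts: Zbtb16 at 0.677 CPM in ALP replicate 3 of batch 2 (next 0.179), and Thy1 at 1.97 CPM in ALP replicate 1 of batch 1 (next 0.609) and at 2.80 CPM in cEILP replicate 2 of batch 1 (next 0.287). Each was picked because its gap to the nearest library was a large share of the range of its group. Of 39 group values examined this way, 6 were picked, and chance picks about 1 in 20 (1.95 of 39).

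The step from ALP to sEILP differed between batches in 2 genes, by a test of the difference itself. Pde3b, a phosphodiesterase gene, had log2 fold changes of -8.31 and -0.37 in batches 1 and 2 (adjusted p = 0.00547), and 0610030E20Rik -7.40 and 0.61 (0.00973). The step from sEILP to cEILP differed in 5 genes. Pde3b (9.10 and 0.77, adjusted p = 0.00391) and 0610030E20Rik (7.17 and -0.52, 0.0211) moved back in batch 1. Both comparisons use the same 2 sEILP libraries of batch 1, so they are not independent. Klhl18 had -11.2 and -0.61 (0.0372), Mia2 -2.64 and -0.09 (0.0321) and Arhgef18 -1.82 and 0.74 (0.0352). These fitted folds have no floor, so large ones are inexact. Batch, reporter genotype and depth changed together, so the origin cannot be told.

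The commitment step, from sEILP to cEILP, called fewer genes in batch 2. Fitted for each batch alone, it called 28 genes in batch 1 and 0 in batch 2 by edgeR, with 1352 and 852 genes at an unadjusted p under 0.05. Of the 71 genes called from both batches together, 70 had the same sign in both, and all 71 had an unadjusted p under 0.05 in batch 1 and 53 in batch 2. Libraries with few detected genes were argued against as the cause: without the 3 such libraries batch 2 still called 0 genes, and batch 1 called 69. Smaller differences in batch 2 stay open. The 182 genes changed by forced NFIL3, signed by that change, moved by a mean of 0.94 (SE 0.16) in batch 1 and 0.54 (SE 0.09) in batch 2. The difference of -0.40 (SE 0.15) lay between the bounds set for and against. These SE come from the spread over genes, which are not independent, and leave out the spread between libraries. No biological explanation was tested.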

How the results depend on the processing

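The tests without the 3 libraries with the fewest genes, with quality weights, with a robust fit and with a library moved to cEILP, as well as the counts over other splits, were chosen only after the results were seen.

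The named genes, signature medians, score and correlation kept their sign under the alternatives tried for each. Among lists that did not pass in either setting, the direction turned with fry or the replicate block for dendritic genes in NFIL3 against GFP, stromal and immediate early genes in sEILP against ALP, B lineage and cholesterol synthesis genes in cEILP against sEILP, stromal and E and Id protein genes in ILCP against cEILP, and circadian genes in NFIL3 against cEILP. The larger share of called genes turned from higher to lower or back in sEILP against ALP, cEILP against sEILP and ILCP against cEILP, under the settings given with those counts above, and in cEILP against sEILP also with a library moved to cEILP (21 higher, 3 lower). The signatures of sEILP, cEILP and ILCP kept their call in NFIL3 against GFP under all of theirs. Medians of raised and lowered genes ran from 1.37 to 2.52 and from -0.88 to -0.14 for sEILP, from 1.45 to 2.04 and from -0.44 to -0.37 for cEILP, and from 0.95 to 1.07 and from -0.84 to -0.47 for ILCP. DESeq2 size factors, no filter, a log2 fold change of at least 1 and the robust fit left each of the 6 counts within 1.5 times its value, as did the additive batch term for the 2 comparisons it covers (207 and 56). With the replicate block the counts were 143 for NFIL3 against GFP, 50 for cEILP against sEILP, 286 for ILCP against cEILP, 304 for GFP against ALP and 191 for NFIL3 against cEILP, within 1.5 times, and 119 for sEILP against ALP, which was not; the cause was not tested.

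Other tools called more genes in each comparison, and limma-voom lost many of the calls made by edgeR. DESeq2 called 817 genes in NFIL3 against GFP, 1141 in sEILP against ALP, 799 in cEILP against sEILP, 1245 in ILCP against cEILP, 1157 in GFP against ALP and 1217 in NFIL3 against cEILP, with 181 of 182, 197 of 197, 71 of 71, 375 of 378, 374 of 377 and 237 of 237 edgeR calls among them. On simulated data 172 of 249 and 252 of 355 DESeq2 calls were false. Limma-voom called 462 in sEILP against ALP, 153 in cEILP against sEILP, 1523 in ILCP against cEILP and 386 in NFIL3 against cEILP, and it moved the median of all genes to -0.21, 0.06, -0.28 and 0.15. It called 255 in NFIL3 against GFP and 526 in GFP against ALP. In the order used for DESeq2, it shared 70 of 182, 127 of 197, 35 of 71, 354 of 378, 221 of 377 and 124 of 237 edgeR calls. With quality weights it called 821, 800, 275, 1113, 1098 and 660, in the same order, and shared 139, 180, 53, 316, 320 and 172. Fitting the compared libraries alone called 80 in NFIL3 against GFP (46 shared), 124 in ILCP against cEILP (80 shared) and 100 in NFIL3 against cEILP (67 shared), but 380 in GFP against ALP (225 shared), also 3 against 3 libraries, 89 in cEILP against sEILP (41 shared) and 307 in sEILP against ALP (151 shared). The cause was not tested.

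The libraries mattered too. Batch 1 alone called 41 genes and batch 2 alone 61 in sEILP against ALP, and 28 and 0 in cEILP against sEILP (852 at an unadjusted p under 0.05 in batch 2; no other tool was run on a batch alone), from fewer samples. Without the 3 libraries with fewest genes, sEILP against ALP called 309 and cEILP against sEILP 129, cause not tested. NFIL3 against GFP (331) and GFP against ALP (644) hold none of the 3, so only the shared fit could change. With sEILP replicate 2 of batch 1 as cEILP, cEILP against sEILP called 24 genes, 1 among the 71. Leaving out each library in turn gave 108 to 187 genes in NFIL3 against GFP, lowest without NFIL3 replicate 2, and 137 to 202 in sEILP against ALP. It gave 32 to 80 in cEILP against sEILP, lowest without cEILP replicate 1 of batch 2, and 225 to 419 in ILCP against cEILP, lowest without cEILP replicate 3. It gave 227 to 303 in GFP against ALP, lowest without ALP replicate 3, and 150 to 229 in NFIL3 against cEILP, lowest without NFIL3 replicate 2. The counts also moved by over 1.5 times without GFP replicate 1 (116) or 2 (119) or NFIL3 replicate 1 (114) in NFIL3 against GFP, sEILP replicate 1 (40) or cEILP replicate 3 (37) of batch 2 in cEILP against sEILP, cEILP replicate 1 (242) or 2 (241) in ILCP against cEILP, and GFP replicate 2 (238) in GFP against ALP. Where this left 1 sEILP library in batch 1, it was assumed to vary like the other groups.

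With an estimated correlation between genes, 6 of 13 lists still passed in NFIL3 against GFP, 4 of 7 in GFP against ALP and 4 of 9 in NFIL3 against cEILP; the cause was not tested. The score of NFIL3 over GFP, 2.85, was 3.31 with 50 genes each way and 2.7 to 3.1 with a library left out. The correlation of 0.19 between NFIL3 against GFP and cEILP against ALP was 0.60 over the genes that passed in the latter, a choice of genes that raises it. For 185 results on named genes, 3297 values were computed: 2537 stayed on their side of the threshold, 753 lost the call, 7 gained it and 0 changed sign. Of these results 35 kept their call under every alternative and 148 lost it under at least 1.

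Whether chance could give such counts was read from other splits of the same libraries. For sEILP against ALP the real split called 197 genes and the highest other 12, and for cEILP against sEILP 71 and 14. In each case 1 of 40 splits drawn from 350 and from 200, the real one, called as many. This argues against chance for the count as a whole. It is the smallest share that 40 splits can give, and it does not bear on single genes. Groups of 3 against 3 give 10 splits, too few for a share under 0.05; the real and highest other counts, with 1 of 10 splits calling as many, were 182 and 1 in NFIL3 against GFP, 378 and 1 in ILCP against cEILP, 377 and 1 in GFP against ALP, and 237 and 6 in NFIL3 against cEILP.

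Depth limits the low genes. A group at 0 counts lies under a floor of 3 counts per library, or 0.186 to 0.545 CPM, and folds against it are lower bounds. On simulated data at 3 against 3 libraries, edgeR recovered 8 of 50 genes at 4-fold and 22 at 16-fold.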

Other observations

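All tests in this part, the 4 further comparisons and those on the 2 patterns weighed below, were chosen or read only after the main results were seen.

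The whole path from ALP to the committed progenitor and to ILCP shows more genes than its single steps. From ALP to cEILP 701 genes passed (319 higher, 382 lower). Tox rose by 4.37 (adjusted p = 1.50e-09), Id2 by 4.78 (4.95e-08), the gate gene Zbtb16 by 9.31 (6.98e-07), Rora by 7.68 (1.55e-05) and Cpa3 by 7.18 (8.44e-07). The mitotic genes Ccnb1 (-1.74, 3.03e-06) and Cdc20 (-1.57, 8.41e-06) fell, and 13 of 22 cell cycle genes fell (median -1.26, camera adjusted p = 2.19e-22, and 0.000469 with an estimated correlation). From ALP to ILCP, in batch 2, 959 genes passed (395 higher, 564 lower). Of 18 regulators 12 rose, and Id2 rose by 6.56 (6.66e-08), Tox by 4.90 (1.41e-08) and Gata3 by 7.28 (0.000160). ILC2 genes (8 of 12 rose) and ILC3 and LTi genes (6 of 13 rose) ranked higher, while 12 of 20 multipotent progenitor genes fell, among them Cd34 (-4.81, 1.21e-07). Each gene named here passed with any 1 library left out. The counts ran from 461 to 625 and from 683 to 904 with a library left out, and cEILP against ALP fell by over 1.5 times without cEILP replicate 1 of batch 2 (461).

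Compared with uncultured, otherwise sorted ALP of batch 1, NFIL3 cells had 420 genes pass (232 higher, 188 lower). Of 18 regulators 9 rose (median 5.42), with Tcf7 at 8.23 (3.10e-05), Id2 at 5.43 (6.43e-06), Tox at 2.93 (5.48e-05) and Rora at 8.17 (0.00226). Il2rb (12, 3.64e-05) was among 6 of 20 NK genes that rose. The gate gene Flt3 (-6.81, 0.000926), Dntt (-10.47, 0.000293) and Cd34 (-3.78, 6.13e-06) fell. Glycolysis genes ranked higher (8 of 15 rose, median 1.17, adjusted p = 5.61e-16, and 0.00156 with an estimated correlation), Aldoa by 1.77 (4.63e-06). Against sEILP, 153 genes passed (75 higher, 78 lower). There 3 of 20 progenitor genes fell, among them Cd34 (-3.35, 0.000124) and Cd93 (-2.49, 0.00457), and Eno1 rose (1.68, 0.000124). Of 18 regulators 0 passed (1 over the list alone, median 2.22). Each gene named here passed with any 1 library left out. The counts ran from 276 to 333 against ALP and from 89 to 128 against sEILP. They fell by over 1.5 times without ALP replicate 1 (276) or NFIL3 replicate 2 (279) against ALP, and without sEILP replicate 1 (91) or NFIL3 replicate 1 (89) or 2 (95) against sEILP.

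MHC class I genes were higher in NFIL3 than in GFP, with a median of 1.08 over 14 genes (SE 0.25), 13 of them above 0. Each SE in this paragraph comes from the spread over genes, which are not independent, and leaves out the spread between libraries. An interferon response stays open: 16 interferon stimulated genes had a median of 0.20 (SE 0.36) but went both ways, 10 of them above 0, with a spread of 1.14, larger than the gap to the MHC class I median. Library scaling stays open too: the excess over all genes was 1.08, and DESeq2 size factors gave 1.05, but both scalings hold the median of all genes near 0, so a shift of all other genes cannot be told apart from a rise of these 14. A candidate explanation is a loss in the cultured control that was smaller in NFIL3 cells. The MHC class I median was -1.07 in GFP against ALP and -0.27 (SE 0.09) in NFIL3 against ALP. The latter was below 0 but within a tolerance set after the values were seen. This was found and tested on the same libraries. No virus-free ALP culture was analysed here, so effects of NFIL3, the control virus and the sort stay open.

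The authors' deposited mean for cEILP includes a library labelled sEILP, replicate 2 of batch 1. A wrong label was argued against: on the 50 raised and 50 lowered genes with the smallest p of cEILP against sEILP in batch 2, where 0 genes passed by edgeR (852 at an unadjusted p under 0.05), the library lay at 0.148 on a scale from 0 (the other sEILP library of batch 1) to 1 (cEILP), where the lowest cEILP library lay at 0.876 and the SD of cEILP was 0.125. Whether the deposited tests also moved it stays open, since the deposited log2 fold changes of sEILP against ALP lay closer to the means without the library in 56.0% of 12373 genes, with a median distance of 0.241 against 0.273. No biological explanation was tested.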
